A study of Homo sapiens with 8 samples.

How the data were processed

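The series measured RNA in 8 bone marrow metastases of castration-resistant prostate cancer, which is prostate cancer that grows despite low androgen. Per the labels' protocols, RNA came from frozen biopsies, was depleted of ribosomal RNA, was amplified as cDNA from a small amount of total RNA with a NuGEN Ovation kit, and was made into paired-end NEBNext libraries. The labels give 1 group, so no contrast between groups was possible. They give fragments of 150 bp for 2 libraries and 300 bp for 6. Replicate numbers 1 to 8 follow the order of deposit and only name a library. The labels name separate patients, so the spread between libraries includes differences between tumours and biopsies.

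Each library had a feature table and a list of splice junctions. Per the file headers, the feature tables hold deposited counts of uniquely mapped and shared reads for every transcript, exon and intron, and the authors' RPKM values, which are reads scaled to transcript length and to the reads used for normalization. These tables mix text and number lines. In the junction lists, the deposited counts of reads per junction were used. The submitters' processing notes name the hg19 genome build, and all coordinates are on it. The format of the headers is that of the RUM aligner, and its settings are not given in the sources used here. The kit and the files do not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Depth ran from 39668618 to 103215283 reads used for normalization. Counting intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

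The tables held 193511 transcripts, of which 122152 matched a gene symbol. Of 35577 RefSeq transcripts, 32850 matched by accession. Names came from a RefSeq gene table and GENCODE annotation of another build, used for names alone. Each of 28598 genes was represented by its longest RefSeq transcript, or its longest Vega transcript where there was none. Levels were recomputed as RPKM from unique plus shared reads. Introns were called clean when they overlapped no annotated exon of another transcript, which left 913797 of 1392090 introns. The intron share was the percent of exon plus clean intron reads that fell in introns, over 6528 genes with a mean exon RPKM of at least 1 and at least 1000 bases of clean intron. The intron ratio of a gene was log2 of clean intron density over exon density, each with a pseudocount of 0.1 RPKM, minus the library's median. This scale understates differences of low genes.

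Gene ratios were tested against a change of 1 log2 unit with limma treat in a one-sample fit, with Benjamini-Hochberg adjustment at 0.05. For lists with at least 3 tested members, the median difference from genes in the same bin of exon level (10 bins) and intron length (5 bins) was tested with an exact two-sided sign-flip test over 256 patterns, adjusted over 13 lists. The smallest p it can give is 0.00781 with 8 libraries, 0.0156 with 7 and 0.0312 with 6. List scores are the mean log2(RPKM + 0.1) of the members, set beside 10000 random lists of the same size. Correlations used exact two-sided permutation over 40320 pairings, adjusted over a family of 12. Fragment sizes were compared with an exact two-sided permutation test over 28 splits, whose smallest p is 0.0714, so it cannot reach 0.05.

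The limma step was tested on simulated counts for 6528 genes, of which 50 at each of 4 shifts were changed. It called 98.0% of genes raised by 2 log2 units and 100% of those raised by 3, but 30.0% of those lowered by 2 and 74.0% of those lowered by 3, and 0 of 6328 unchanged genes. Unchanged genes were given 1 common ratio per library and 1 noise level, so the 0 says little about false calls in the data. The median estimate was -1.15 for a shift of -2 and -1.89 for a shift of -3, so low ratios are understated and undercounted. The exact tests matched scipy's permutation tests. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, limma 3.58.1 and matplotlib 3.10.9.

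Lists, named-gene rules, tests and alternatives were fixed before the data were examined, except where stated. The 26 lists held 378 entries, of which 375 were measured. Levels were tabulated for up to 4 members of each list with the highest median and for genes fixed in advance (KLK3, FOXA1, HOXB13, ERG, ETV1, NR3C1, AKR1C3, CYP17A1, MKI67 and CHGA). They were also tabulated for the 10 genes with the largest median absolute deviation at a median RPKM of at least 5. The text gives a selection of these genes, and some other list members, chosen after the values were seen. Intron ratios are given for the 10 highest and 10 lowest genes past the threshold and on 1 side of 0 in all 8 libraries, and for KLK3, KLK2, TMPRSS2 and FKBP5. Some planned results, including 4 of the 12 correlations, are not reported here. Y-linked genes, XIST, HLA genes, immunoglobulin and T cell receptor segments and genes with common germline deletions were left out because they can mark a person. GYPB and other blood group or copy-number-variable genes were added to those left out after the data were seen. The level filters were run again after the data were seen, with the library medians of the main analysis. The alternatives fixed in advance changed the introns, transcript, pseudocount, level filter, read mapping, fragment size and libraries. Each run with fewer libraries or another level filter chose the tested genes and the matching bins anew.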

Results

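RNA-seq libraries of 8 bone marrow metastases of castration-resistant prostate cancer were compared within 1 group. Reads used for normalization numbered from 39668618 to 103215283 per library. Pairwise correlations of log2 levels over 8191 expressed genes ran from 0.439 to 0.801 across 28 pairs, so no 2 libraries were copies of each other.

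Many prostate and androgen-regulated genes were abundant in the metastases. The androgen program, a list of 27 androgen-regulated genes, had a mean score of 1.95 ± 0.84 (SD, n = 8), above all of 10000 random lists of the same size. KLK3, which encodes prostate-specific antigen (NM_001030047, chromosome 19, 51358171 to 51364020), had 126 ± 105 RPKM (SD, n = 8) and ran from 11.9 to 279. KLK2 had 41.4 ± 32.1 RPKM and ACSL3 had 31.1 ± 23.4 (SD, n = 8 each). The list of prostate and epithelial identity genes scored 1.74 ± 0.82 (SD, n = 8), also above all random lists. In it, FOLH1, which encodes prostate-specific membrane antigen, had 79.0 ± 72.0 RPKM, GOLM1 had 42.9 ± 27.3, STEAP1 had 41.4 ± 28.7 and EPCAM, an epithelial adhesion molecule, had 41.1 ± 30.2 (SD, n = 8 each). FOXA1 had 6.90 ± 4.66 RPKM and HOXB13 had 1.25 ± 0.75 (SD, n = 8). Of the 21 members of this list, 14 had a median of at least 1 RPKM. KRT8, SPDEF, HPN, CLDN3 and SPINT1 stayed below 1 RPKM in every library, with highest levels of 0.641, 0.253, 0.281, 0.111 and 0.855.

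The glucocorticoid receptor NR3C1 had 1.98 ± 1.25 RPKM, NR3C2 had 0.580 ± 0.901 and ESR1 had 0.129 ± 0.084 (SD, n = 8). Of the androgen synthesis and turnover genes, whose list scored -1.36 ± 0.28, HSD17B4 had 60.9 ± 62.4 RPKM, SRD5A1 had 1.15 ± 0.93, SRD5A3 had 0.904 ± 0.339 and AKR1C3 had 0.936 ± 1.554 (SD, n = 8). The median was 42.1 for HSD17B4 and 0.354 for AKR1C3, and the highest library had 213 and 4.70. CYP17A1, a steroid synthesis enzyme, did not exceed 0.175 RPKM in any library. The ETS factor ERG ran from 0.219 to 2.13 RPKM and ETV1 from 0.125 to 0.723. ETV4, another ETS factor, reached 4.93 RPKM and was at 1 RPKM or more in 2 libraries, with a median of 0.0316.

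Mitotic and S-phase genes scored 0.49 ± 0.70 (SD, n = 8), at the 99.97th percentile of random lists, with TOP2A at 11.2 ± 6.4 RPKM, EZH2 at 8.03 ± 3.65 and MKI67 at 4.83 ± 4.03. Genes often altered in prostate cancer scored 0.86 ± 0.29, with CCND1, which encodes cyclin D1, at 52.3 ± 39.1 RPKM (SD, n = 8). The neuroendocrine list scored -1.97 ± 0.51, at the 2.04th percentile. Of its members with the highest medians, SCG3 reached 2.13 RPKM and ONECUT2 1.81. ENO2, at 18.1, and NCAM1, which NK cells also express, at 5.35, were highest in the library with T and NK cell markers described below, against at most 1.18 and 3.79 in the other 7. No median exceeded 0.598, and CHGA, a neuroendocrine granule protein, did not exceed 0.104. Of the other members, SYT4 reached 11.5 RPKM, DDC 7.26 and CHGB 5.37, with medians of at most 0.156. The basal epithelial list scored -1.84 ± 0.21, with ITGA6 at 7.31 ± 2.50 RPKM and DST at 5.60 ± 3.86 (SD, n = 8), while TP63 did not exceed 0.615 and LAMB3 did not exceed 0.183.

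Of the marrow and stromal lists, bone matrix genes stood highest, at 1.95 ± 1.40 (SD, n = 8). IBSP, bone sialoprotein, ran from 3.97 to 1032 RPKM, SPARC from 6.39 to 295 and SPP1 from 3.66 to 248. Erythroid genes scored -1.19 ± 1.05, and HBB, a haemoglobin chain, ran from 1.95 to 227 RPKM. HBA1 and HBA2, also of this list, reached only 4.54 and 5.28 RPKM. Whether the members of a list were recovered equally was not tested, so a low score does not show that a cell type was absent. The macrophage list scored -1.12 ± 0.83, the neutrophil list -1.95 ± 0.87, the B and plasma cell list -2.80 ± 0.23, the megakaryocyte list -2.22 ± 0.24, the osteoclast list -1.88 ± 0.68, the endothelial list -1.71 ± 0.50, the adipocyte list -1.69 ± 0.27 and the skeletal muscle list -2.02 ± 0.61 (SD, n = 8 each). T and NK cell genes scored from -2.98 to -2.21 in 7 libraries and 4.56 in 1. In that library GZMA, a cytotoxic granule protease, reached 417 RPKM, against at most 0.447 in the others. The same library had the lowest prostate and epithelial score, -0.10 against 1.60 to 2.61, and the lowest androgen program score, 0.44 against 1.16 to 2.91. It had the highest mitotic and S-phase score, 1.48 against at most 1.14, and the highest MKI67 level, 13.5 RPKM against at most 6.20.

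**Figure D1:**
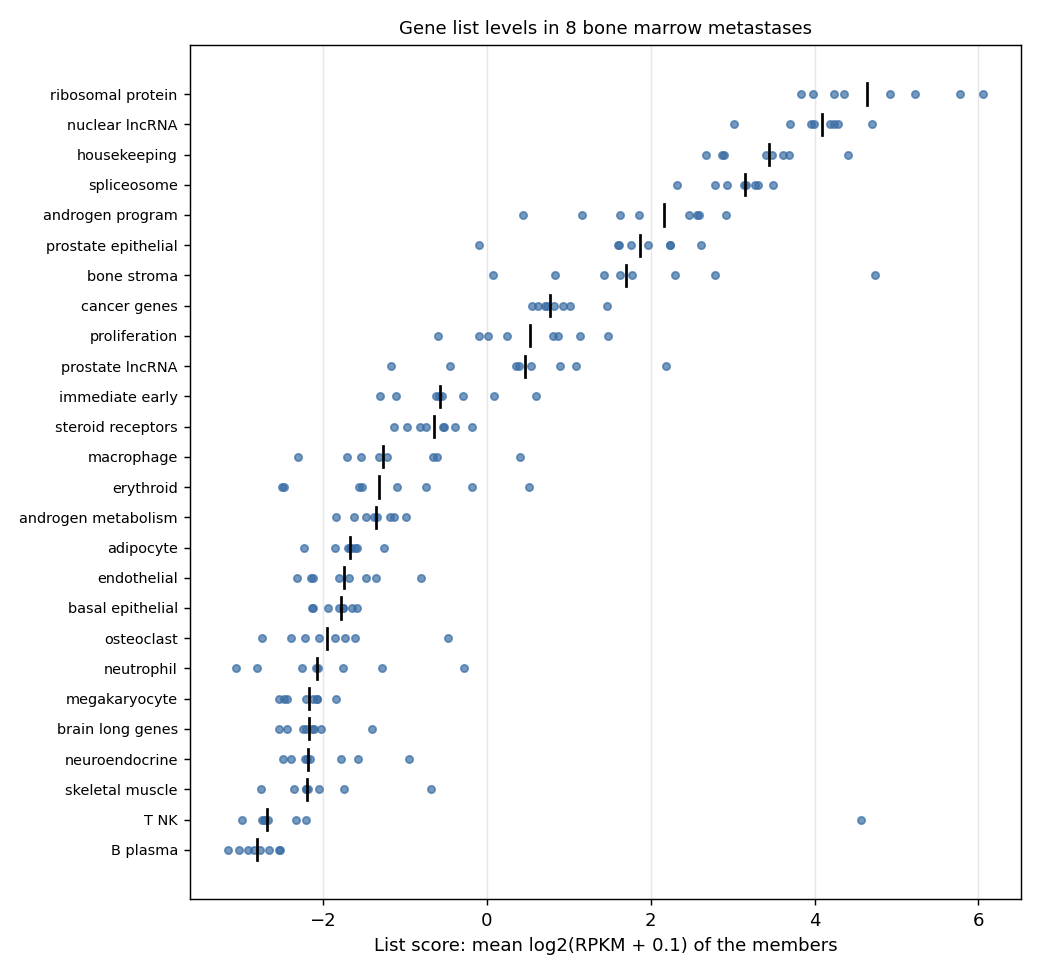
Scores of 26 gene lists in 8 libraries, as the mean log2(RPKM + 0.1) of the members on the horizontal axis, with 1 point per library and a bar at the median. The T and NK list has 1 point at 4.56 and the other 7 between -2.98 and -2.21.

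The nuclear long noncoding RNAs scored 4.01 ± 0.50, with MALAT1 at 3256 ± 1224 RPKM and NEAT1 at 168 ± 68. Ribosomal protein genes scored 4.80 ± 0.83, broadly expressed genes 3.38 ± 0.56 and splicing factors 3.05 ± 0.37 (SD, n = 8 each). The prostate noncoding RNAs scored 0.48 ± 1.005, steroid receptors -0.66 ± 0.31, immediate early genes -0.47 ± 0.61 and long neuronal genes -2.13 ± 0.34 (SD, n = 8 each). In all, 9 of the 26 lists lay above the 95th percentile of random lists. The genes with the largest deviation between libraries were led by TMEFF2, at 0.632 to 547 RPKM, CRISP3, at 0.209 to 246, and PLA2G2A, at 0.327 to 156.

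Introns took 53.5% ± 6.4 (SD, n = 8) of the reads in expressed genes. The share ran from 41.7% to 58.6%. It was 69.5% over all introns, which include bases of overlapping exons, and 44.3% in genes of at least 5 RPKM. In the median library, the median gene had an intron density of 13.5% of its exon density.

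Single genes differed widely in intronic signal. Of 6528 genes tested with limma, 542 had a ratio of intron to exon density higher than the median gene by over 1 log2 unit and 710 had a lower one, and 1235 of these 1252 lay on 1 side of 0 in all libraries. The lowest were CCND1, at -5.57 ± 0.48 (SE, limma adjusted p = 2.72e-05), the chaperone gene HSP90AA1, at -5.27 ± 0.26, and YWHAE, at -5.12 ± 0.27. LINC02503, AC097534.1, LINC01609, RAB13, RPS20, MARCKS and UGDH-AS1 followed, down to -4.13. The highest were LSAMP-AS1, at 7.33 ± 0.58 (SE), AP006222.1, at 5.60 ± 0.35, and SLC45A2, at 5.01 ± 0.52. AC114321.1, TTL, FAM210A, SHROOM1, EMBP1, AL136320.1 and LINC01322 followed, down to 3.93. Each of these ratios rests on 1 transcript per gene, whose bounds set the bases counted as intron. For HSP90AA1 these were 39043 bases of a transcript from 102547075 to 102606086 on chromosome 14. With the transcript of highest median level, 842 of the 1088 main calls tested were called again. LSAMP-AS1 lies inside LSAMP, AL136320.1 overlaps CELF2, AC097534.1 overlaps GALNT7, UGDH-AS1 overlaps SMIM14 and RPS20 overlaps SNORD54, so their reads are uncertain. SLC45A2 (33945972 to 33984780) lies just downstream of AMACR (chromosome 5, 33987091 to 34008220) on the same strand. AMACR had 33.9 ± 28.6 RPKM (SD, n = 8), and whether its reads extend into SLC45A2 was not tested. The 10 highest genes had mean exon levels of 1.04 to 2.14 RPKM, close to the filter of 1 RPKM, which is also the denominator of their ratio. LSAMP-AS1, AC114321.1, AL136320.1 and LINC01322 reached 1 RPKM in only 1 library each, so they were tested because of that library. Without a level filter, the split of calls depended on the library median that was taken off. That setting raised the medians by 1.98 on average and gave 681 higher and 4658 lower, but 12478 higher and 821 lower with the medians of the main analysis. With a pseudocount of 1 RPKM there were 64 higher and 560 lower. This raised the medians by 1.20 on average and also changed every ratio. It was not run with the medians of the main analysis, so these effects cannot be told apart.

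Of the androgen-responsive genes KLK3, KLK2, TMPRSS2 and FKBP5, none passed the threshold in the main analysis. FKBP5 had a ratio of 1.28 ± 0.11 (SE) with limma adjusted p = 0.0673, TMPRSS2 had 0.58 ± 0.15, KLK2 had -0.65 ± 0.18 and KLK3 had -1.09 ± 0.21. With all introns, FKBP5 passed as higher (1.82, limma adjusted p = 0.000141) and so did KLK2 (1.91, limma adjusted p = 0.00842). All introns include bases of overlapping exons, whose reads may raise these ratios. FKBP5 turned to -0.94 with the transcript of highest median level and passed without replicate 1 (1.30, adjusted p = 0.0455). Other changes of call matched or fell short of the change in the library median taken off every gene, so they are not evidence about these genes. They were FKBP5 with a pseudocount of 0.01 (1.43, adjusted p = 0.01004) and with unique reads (1.33, adjusted p = 0.0293), KLK3 with a pseudocount of 1 (-2.03, adjusted p = 0.0117), and KLK2 and KLK3 without a level filter (-2.64 and -3.08).

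As a list, the androgen program carried more intronic signal than genes matched on exon level and intron length. The difference was 0.60 ± 0.29 log2 (SD, n = 8), higher in 8 of 8 libraries, with an exact sign-flip p = 0.00781 and adjusted p = 0.0339. It lay at the 99.96th percentile of random matched lists. Of its 23 tested members, SLC45A3, C1orf116 and MLPH were higher than the median gene and PMEPA1 was lower, 3 and 1 both over all genes and adjusted over the list alone. Against all genes without matching, the list's median ratio was 0.05, while the median of its gene means was -0.06. With the transcript of highest median level the difference was 0.071 (adjusted exact p = 0.727), and with a pseudocount of 1 it was 0.31 (adjusted exact p = 0.169). Leaving out any 1 of replicates 2 to 8 gave 0.44 to 0.65 with adjusted exact p of 0.0547 to 0.0750, and the 300 bp libraries gave 0.69 with 0.0573.

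The prostate and epithelial list differed by 0.64 ± 0.21 (SD, n = 8; exact p = 0.00781, adjusted p = 0.0339), higher in 8 of 8 libraries, although its median without matching was -0.63. Of its 10 tested members, STEAP2 and GRHL2 were higher and EPCAM, CDH1, GOLM1 and STEAP1 lower, 2 and 4 also adjusted over the list alone. Its difference was 0.23 with a pseudocount of 1 (adjusted exact p = 0.508), 1.24 with the transcript of highest median level (adjusted exact p = 0.0417) and 1.06 in the 300 bp libraries (adjusted exact p = 0.0573). The 300 bp run tested 6238 genes, chosen and binned anew. No library exceeded 0.972 in the main analysis, so the 1.06 is not an effect of fragment size alone. Ribosomal protein genes differed by -1.33 ± 0.33 (SD, n = 8; exact p = 0.00781, adjusted p = 0.0339), lower in 8 of 8 libraries, and 13 of 14 tested members were lower, also adjusted over the list alone. The difference was -1.01 with a pseudocount of 1 (adjusted exact p = 0.102) and -1.26 in the 300 bp libraries (adjusted exact p = 0.0573). Leaving out any 1 of replicates 2 to 8 ended both calls, as for the androgen program, at 0.60 to 0.71 for the prostate list and -1.39 to -1.28 for ribosomal protein genes, with the same range of adjusted exact p from 0.0547 to 0.0750. Before adjustment, the smallest exact p is 0.0156 with 7 libraries and 0.0312 with 6. The end of a call in fewer libraries thus does not show that single libraries carried it. Splicing factors, at -0.27 ± 0.24 (exact adjusted p = 0.0508, n = 8), and bone matrix genes, at -0.63 ± 0.56 (exact adjusted p = 0.0812, n = 8), did not pass, nor did the other 8 lists. With a pseudocount of 0.01, bone matrix genes (-0.91, adjusted exact p = 0.0169), mitotic and S-phase genes (-0.55, adjusted exact p = 0.0169), neuroendocrine genes (-1.14, adjusted exact p = 0.0169), macrophage genes (-0.57, adjusted exact p = 0.0254) and broadly expressed genes (-0.34, adjusted exact p = 0.0339) passed as lower. All of these except the neuroendocrine list also passed as lower with all introns, at -0.75, -0.62, -0.75 and -0.79 in the same order. The sign-flip test asks whether a list's difference keeps 1 side across libraries, not whether other matched genes differ as much. In the main analysis, bone matrix (12 tested genes) and mitotic genes (12) lay at percentiles 0.54 and 5.2 of random matched lists. Neuroendocrine (4), macrophage (3) and broadly expressed genes (7) lay at 22.97, 22.79 and 24.86, and splicing factors at 12.17, so these did not stand out. Bone matrix, mitotic and broadly expressed genes also passed as lower at 5 RPKM and without replicate 1, and broadly expressed genes with the transcript of highest median level (-0.62, adjusted exact p = 0.0417). Without replicate 1, 6341 genes were tested in place of 6528, in matching bins made anew. Passes in that run thus cannot be laid to the missing replicate alone. The difference of the splicing factors was -0.28 without replicate 1 (adjusted exact p = 0.0268, n = 7) and -0.29 with a pseudocount of 0.01 (adjusted exact p = 0.0254, n = 8), and turned to 0.96 with all introns (adjusted exact p = 0.0156, n = 8). All introns include bases of overlapping exons, which limits what this turn says. Of the splicing factors, 9 of 19 were lower over all genes, and adjusted over the list alone 1 was higher and 9 lower. Of the bone matrix genes, 6 of 12 were lower, and adjusted over the list alone 1 was higher and 6 lower.

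**Figure D2:**
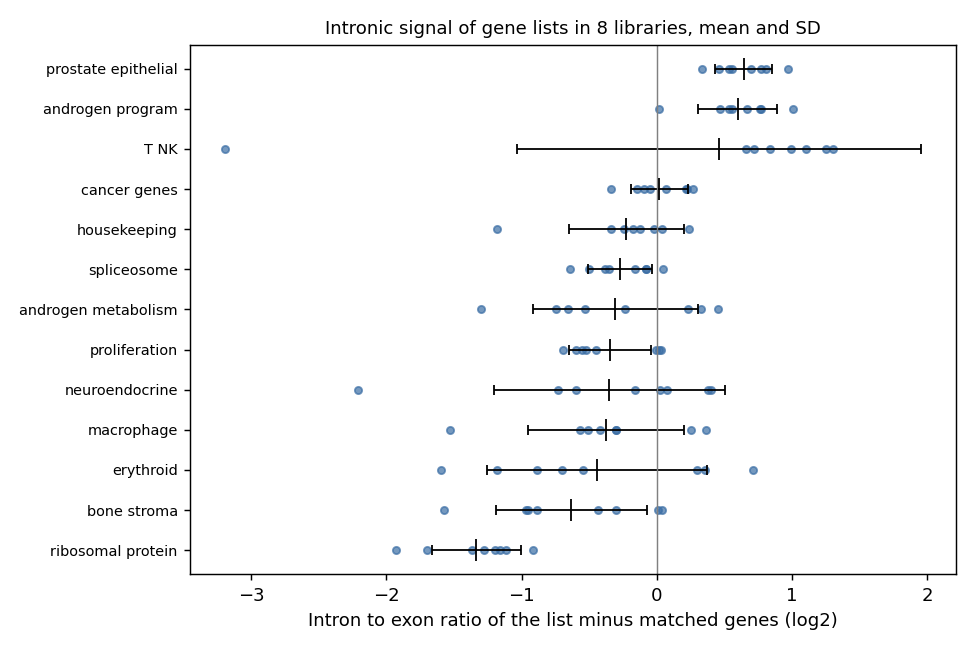
Difference in log2 intron to exon ratio between each list and matched genes, with 1 point per library and the mean and SD of 8 libraries. The androgen program and prostate epithelial lists lie above 0 in all 8 libraries and ribosomal protein genes below 0 in all 8.

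Intronic signal did not differ detectably between the ends of genes. Over 3168 genes, the first intron differed from the last by 0.02 ± 0.04 log2 (SD, n = 8; exact sign-flip p = 0.195), with 6 of 8 libraries above 0. It turned to -0.067 in genes of at least 5 RPKM (exact p = 0.0859). Without replicate 7 the value was 0.03 (exact sign-flip p = 0.0469, n = 7).

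Libraries had 172623 ± 23381 junctions (SD, n = 8), of which 58.1% ± 8.3 were annotated in the files' transcripts. Among junctions with at least 3 reads there were 81522 per library and 88.5% were annotated. Between fragment sizes, the intron share was 56.1% at 150 bp and 52.7% at 300 bp (exact permutation p = 0.929, n = 2 and 6). The median clean intron level of the tested genes was 0.473 RPKM at 150 bp and 0.358 at 300 bp. Its exact permutation p of 0.0714 is the smallest this test can give, and no other library measure compared reached it. A link between intron level and fragment size thus stays open.

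None of the 8 correlations across libraries given here passed the adjustment over 12, and 1 had an unadjusted Pearson p and 1 an unadjusted Spearman p under 0.05. The intron share and the library depth had rho = 0.76 (exact permutation p = 0.0368, adjusted p = 0.302) and r = 0.37 (exact permutation p = 0.347, adjusted p = 0.534). The intron share and the splicing factor score had r = -0.39 (exact permutation p = 0.337, adjusted p = 0.534). Without the 2 libraries farthest in intron share, r was -0.80 (exact permutation p = 0.0528, adjusted p = 0.489). The prostate and mean marrow scores had r = -0.72 (exact permutation p = 0.0370, adjusted p = 0.222) and rho = -0.62 (exact p = 0.115, adjusted p = 0.302), with r = -0.52 without the 2 farthest, -0.37 within 300 bp and -0.41 without the T and NK library, none of them past the adjustment. Without the T and NK library, the proliferation score had r = 0.80 with the androgen program (exact permutation p = 0.0367, adjusted p = 0.201, n = 7) and 0.82 with the prostate score (exact permutation p = 0.0310, adjusted p = 0.201, n = 7), against 0.036 and -0.24 in all 8. The 150 bp libraries, 2 in number, were too few for a value of their own.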

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

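All tests of explanations in this part except those of genomic DNA over all 8 libraries, multiply mapped reads and transcription were chosen after the results were seen. Of 187 sets of 8 library values, 26 had 1 library far from the rest, and 16 of these 26 were in the same library. Chance alone flags about 1 in 20 sets, and sets that share genes are not independent.

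The library in question had a T and NK cell score of 4.56, against at most -2.21 in the other 7. Its log2 levels were 8.71 for GZMA, 6.86 for the chemokine CCL5 and 4.47 for TRAT1, and B2M was at 9.47 against at most 6.90. CD3E had 39.7 RPKM, GNLY 63.7 and CD8A 32.9, each at most 0.238 in the other 7. Of the 14 genes of the list, 0 had a median of 1 RPKM or more. The marrow biopsy as a whole is a poor account, because of the erythroid, neutrophil, macrophage, B and plasma cell and megakaryocyte scores, 0 of 5 lay more than 1 log2 unit above the other libraries. In this library, 8 of 14 prostate-restricted genes were at 1 RPKM or more. That argues against a library without prostate cells only if these reads were not carried over. Prostate reads carried over from other libraries remain open, since the largest share a gene needs was 8.57 times the smallest share another allows, but only 1.67 times without PCA3. A candidate explanation is a biopsy with many cytotoxic T or NK cells. No biological explanation was tested, as the labels give 1 group.

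The same library stood apart in its prostate epithelial score of -0.10, in the intron ratio of broadly expressed genes, -1.18, and in the long neuronal gene score of -1.40. Its log2 levels of STEAP1 (0.92) and MALAT1 (9.77) were the lowest, and those of ENO2 (4.19), MYH7 (-2.001) and CYP17A1 (-1.86) were the highest, the last 2 near the floor. This library also had the highest background ratio, 0.732, of the 2 where genomic DNA stays open below, and its long neuronal genes had a median exon level of 0.292 RPKM, above its 0.150 for MYH7 and 0.175 for CYP17A1. DNA may thus account for the neuronal score and for these 2 genes, which was not tested. Its intron ratios of RAB13 (-2.28) and MARCKS (-0.41) were the highest. The intron ratio of the T and NK list, -3.19 there, is no separate finding, since none of the 10 tested members exceeded 0.478 RPKM in the other 7 libraries (the level of CCL5).

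In the other 7 libraries, 1 library each stood apart in the first to last intron ratio (0.12), the intron ratio of the neuroendocrine list (-2.21) and that of LINC01322 (0.67). The last is no separate finding, since LINC01322 had 14.1 exon RPKM in 1 library and at most 0.0895 in the other 7. Log2 levels stood apart for SRD5A1 (1.81), NR3C2 (1.52), ITGB3 (2.64), IBSP (10.01), ACP5 (-0.42), MMP9 (0.072) and CHGA (-2.30), the last near the floor.

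Intronic reads in expressed genes have several candidate sources. Genomic DNA predicts that introns of long neuronal genes, which the tissue hardly expresses, are as dense as those of expressed genes. The ratio of medians was at most 0.329 in 6 libraries, which argues against DNA as the main source there, and 0.612 and 0.732 in the other 2, where exons and introns of neuronal genes differed by 1.09 to 1.65 times and DNA stays open. With the background density taken off, the intron share of these 2 libraries was 42.7% to 50.0%. Multiply mapped reads are argued against by a share that kept 0.933 of its size with unique reads. Reads caught during transcription cannot be told apart from other pre-mRNA, with 6 of 8 libraries above 0 in the first to last intron ratio.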

How the results depend on the processing

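The alternatives were fixed before the data were examined, except the background correction and the level filters run with the library medians of the main analysis. Of 125 alternative values of the main results, 102 were unchanged, which means direction and side of the threshold for tests, within 1 SD for values per library, and within 1.5 times for counts. With 1 of 8 libraries left out, the mean of fixed library values cannot move by 1 SD. The junction counts and annotated shares were thus bound to be unchanged, and the 102 is no measure of robustness. For the intron share the bound is not exact, since its genes were chosen anew in each run. The intron share was 69.5% with all introns and 44.3% at 5 RPKM, and 48.7% with the background density of long neuronal genes taken off, which was chosen after seeing the data. Genes with a higher ratio numbered 64 at a pseudocount of 1 and 160 at 5 RPKM, where 187 were lower and fewer genes were tested, and 4658 were lower without a filter, where 681 were higher. These settings changed the library median taken off every gene by 1.20, -0.92 and 1.98 on average. With the medians of the main analysis, 37 were higher and 695 lower at 5 RPKM, and 12478 higher and 821 lower without a filter. The pseudocount of 1 was not run in this way. Of the 1252 calls, 524 were shared at a pseudocount of 1 and 932 with all introns. With the transcript of highest median level, 1088 of them were tested and 842 shared. The androgen program's intron difference fell short at the transcript of highest median level (0.071), a pseudocount of 1 (0.31) and 300 bp (0.69), and leaving out 1 replicate gave 0.44 to 0.65; with 7 or 6 libraries the smallest possible p limits the call. The first to last intron ratio turned to -0.0020 with the transcript of highest median level and -0.067 at 5 RPKM, and leaving out 1 replicate gave 0.012 to 0.032, past the threshold without replicate 7. Junctions with at least 3 reads numbered 81522, with 88.5% annotated. Other causes were not tested.

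Among single genes and lists, FKBP5 turned to -0.94 with the transcript of highest median level and -0.71 without a filter, TMPRSS2 to -1.40 without a filter, and KLK2 to 1.91 with all introns and 0.26 at 5 RPKM. The turns without a filter and at 5 RPKM equal the change in the library median, which moves every gene alike, and are not about these genes. Splicing factors turned to 0.96 with all introns. That setting counts bases of overlapping exons as intron, which also limits the turn of KLK2 to 1.91. Cancer genes turned to -0.040 at a pseudocount of 1, -0.0038 at 0.01 and -0.14 with unique reads, and ran from -0.074 to 0.13 without 1 replicate. The T and NK list turned to -0.00023 at a pseudocount of 1 and -0.068 at 0.01. Correlations that changed sign were the androgen program with proliferation (-0.27 to 0.80 without 1 replicate) and with the neuroendocrine score (0.088 at 300 bp), the prostate score with bone matrix (-0.45 without the 2 farthest libraries, -0.16 to 0.47 without 1 replicate), proliferation with the prostate score (0.88 at 300 bp, 0.76 without the 2 farthest, -0.38 to 0.82 without 1 replicate), and the intron share with the prostate score (0.084 without the 2 farthest). The 0.80 and 0.82 came from leaving out the T and NK library. Other causes were not tested. Depth limits ratios of genes with low intron density, which the pseudocount understates. No paired analysis was possible because there is 1 group.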

Other observations

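The test in this part was chosen after the result was seen. Besides the lists, the most abundant transcripts by median level were MALAT1, at 3185 RPKM, TPT1, a translationally controlled tumour protein gene, at 1457, and NPM1, which encodes nucleophosmin, at 301. H3P6 and H3-3A, at 217 and 216 RPKM, are near-identical copies and share reads.

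Libraries with more annotated junction reads relative to depth had a lower intron share, with r = -0.92 (exact permutation p = 0.00047, n = 8) and rho = -0.90 (exact permutation p = 0.0046). The relation was -0.97 within 300 bp and -0.80 without the 2 farthest libraries. A hypothesis is that both may follow the balance of spliced and unspliced sequence, but the relation, at -0.92, is partly built in, since exon reads enter both measures. Intron reads relative to depth, which hold no exon reads, had r = -0.09 (exact permutation p = 0.835, n = 8) with junction reads, so the test does not decide it.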
